A study of Mus musculus with 10 samples.

How the data were processed

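Nuclei from kidneys of transgenic and wild-type mice were sorted by DNA stain and sequenced by droplet single-nucleus RNA-seq. The authors' matrices of UMI counts per gene and barcode were used as deposited; per the submitters' processing notes they were made with Cell Ranger 6.0.0 and STAR 2.5.1b on mm10. Groups came from the labels. The values are raw counts, and CPM values were computed here from the deposited counts.

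Nuclei with at least 300 genes and at most 5.0% mitochondrial counts were kept, and doublets were called per library with Scrublet at an expected rate of 0.08. It removed 6.93% to 12.4% of nuclei, and 112347 remained. Counts were scaled to 10000 per nucleus, and 3000 variable genes and 40 principal components were corrected between libraries and clustered at a resolution of 1.5 into 48 clusters. Clusters were named from markers fixed before the data were examined, needing 3 markers and 200 nuclei, the latter set after the data were seen. This gave 32 named clusters in 12 classes and 16 clusters without a class name. Classes of 20 or more nuclei per library were summed per library, since nuclei are not replicates. Of the 16, 1 stromal-marker cluster, cluster 6, matched 8 of 12 stromal markers, but its 10 leading genes held more markers of another class. It was kept apart, and shares of unnamed nuclei leave it out. Its 4661 nuclei, against 2257 in the largest stromal cluster, are therefore not in the stromal class.

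Sums were tested with edgeR 4.0.16, glmQLFit and glmQLFTest, TMM and filterByExpr, over all 10 libraries with batch and 1 treatment term for each day, and Benjamini-Hochberg adjustment at 0.05. Shares of nuclei were tested likewise with the library's nuclei as offset, adjusted over classes, and standard errors are those of the fitted log2 ratio. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior of 2. They were tested again with an estimated correlation and with fry, whose outcomes are not given here. In the proximal tubule 28 of 29 lists had 3 or more measured members. DESeq2 1.42.0 was an alternative test. R 4.3.3, Python 3.11.15 and scanpy 1.11.5 were used.

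The code was tested on simulated counts with known changes, in 200 genes at a coefficient of variation of 0.15 and with no batch effect. Far more genes were called in the deposited counts, so the rates below do not describe power there. For the proximal tubule at day 28 it recovered 19.7%, 55.7% and 96.7% of genes changed 1.5, 2 and 4 times, and at day 7 1.67%, 31.7% and 90% of such genes. The first run on the deposited counts came before this test, and its counts of changed genes were the same after it.

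Named genes were the 8 largest rises and 8 largest falls per day in proximal tubule with a mean of at least 10 CPM and all treated libraries on the same side of the controls of their batch, up to 3 members of each list by p, and 9 fixed genes; other classes used 3 and 3 with levels at or above those over all nuclei. Pairs of libraries of a group differed by a chi-square per degree of freedom of 11.9 to 38.9, so none was counted as a duplicate. Alternatives were doublets kept, a minimum of 600 genes, clustering without correction, no batch term, no low-count filter, other normalisation, other tests and leaving out each library. An added one kept only proximal tubule clusters with 2 or more markers of their own among their 10 leading genes. The injured cluster, cluster 15, also met this and was left out by choice, which left clusters 9, 10 and 13. Another kept only the largest stromal cluster, cluster 19. The named-gene rule also took 1 gene that is not reported here, and it was left out of the search for libraries far from their group. Total UMIs per library were 15943707 to 31509447.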

Results

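RNA in single nuclei was counted from kidneys of FVB mice in 10 libraries, to ask how tubule and other kidney cells respond when protein leaks through injured glomeruli. The transgenic mice were POD-ATTAC mice, in which podocyte death can be induced. At day 28 there were 2 wild-type libraries and 4 libraries from transgenic mice, spread over 2 batches. At day 7, in a separate batch, there was 1 library from a saline-treated transgenic mouse and 3 from other transgenic mice. The transgenic libraries other than the saline control are called treated here, though the labels name no agent and do not say whether wild-type mice received it. At day 28 all treated mice were transgenic and all controls wild type, so genotype and treatment cannot be told apart. The series description counts 1 mouse per library. The deposited matrices held 10921 to 16081 barcodes per library, a median of 1170 to 2416 UMIs per nucleus and 818 to 1412 genes. The Y-linked gene Uty lay between 218 and 322 CPM and Xist between 1.24 and 3.86 CPM over all nuclei of the 10 libraries.

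At day 28 podocytes, the filtering cells of the glomerulus, made up 0.141% ± 0.0691 (SD, n = 4) of nuclei in treated libraries and 0.830% ± 0.288 (SD, n = 2) in wild-type libraries. The log2 ratio of shares was -2.52 ± 0.45 (SE), with an adjusted p of 0.00152 in edgeR's quasi-likelihood test, and all 4 treated libraries lay below both wild-type libraries. Within batches the wild-type share was 7.26 times and 4.47 times the treated mean. Without WT day 28 replicate 1 the log2 ratio was -2.17 and the adjusted p 0.0514, and with clustering without correction between libraries it was -4.98 (adjusted p = 0.00559). The podocyte gene Nphs1, which encodes nephrin, measured 31.9 and 14.2 CPM over all nuclei of the wild-type libraries and 0.470 to 4.20 CPM in the treated ones.

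Endothelial nuclei fell from 11.7% ± 4.04 (SD, n = 2) to 2.03% ± 0.466 (SD, n = 4) at day 28, a log2 ratio of -2.51 ± 0.16 (edgeR adjusted p = 2.0e-06). Immune nuclei rose from 1.08% ± 0.0473 (SD) to 4.83% ± 1.33 (SD), a log2 ratio of 2.16 ± 0.51 (edgeR adjusted p = 0.0057). Proximal tubule nuclei rose from 12.5% and 17.4% in the wild-type libraries to 29.6% ± 3.19 (SD), with a log2 ratio of 1.00 ± 0.18 (edgeR adjusted p = 0.00152). The rise lay in clusters 2, 15 and 20, which together held 4.09% and 5.57% of wild-type nuclei and 15.8% to 20.2% of treated nuclei. Cluster 2 matched 3 of 6 S1 markers with 0 among its 10 leading genes, cluster 20 was S3-like with Havcr1 among its leading genes, and cluster 15 was the injured cluster. Clusters 9, 10 and 13, led by markers of the S2, S3 and S1 segments, held 8.45% and 11.8% in wild-type and 10.3% to 13.9% in treated libraries, a log2 ratio of 0.19 ± 0.19 (edgeR adjusted p = 0.327), an alternative chosen after the data were seen. Thin limb fell by 1.41 on the log2 scale and urothelium by 0.97. Of 12 named classes 6 changed. Unnamed clusters other than the stromal-marker cluster held 3.17% of wild-type and 10.3% of treated nuclei. Cluster 7, the largest of them, held 0.581% and 0.674% of wild-type and 4.44% to 7.90% of treated nuclei. The stromal-marker cluster, cluster 6, rose from 2.13% ± 0.355 (SD) to 5.08% ± 0.518 (SD), a log2 ratio of 1.26 ± 0.32 (edgeR adjusted p = 0.00839, and 0.0587 and 0.0736 without WT day 28 replicates 1 and 2). These clusters were counted in no class, and the genes that name a class can themselves differ between groups. Without WT day 28 replicate 1 endothelial nuclei alone passed among the 12 classes, and the adjusted p was 0.0587 for immune, 0.0514 for proximal tubule, 0.0587 for thin limb and 0.140 for urothelium nuclei; that of urothelium was also 0.174, 0.102 and 0.0874 without WT day 28 replicate 2, TG day 28 replicate 2 and TG day 28 replicate 3.

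**Figure D1:**
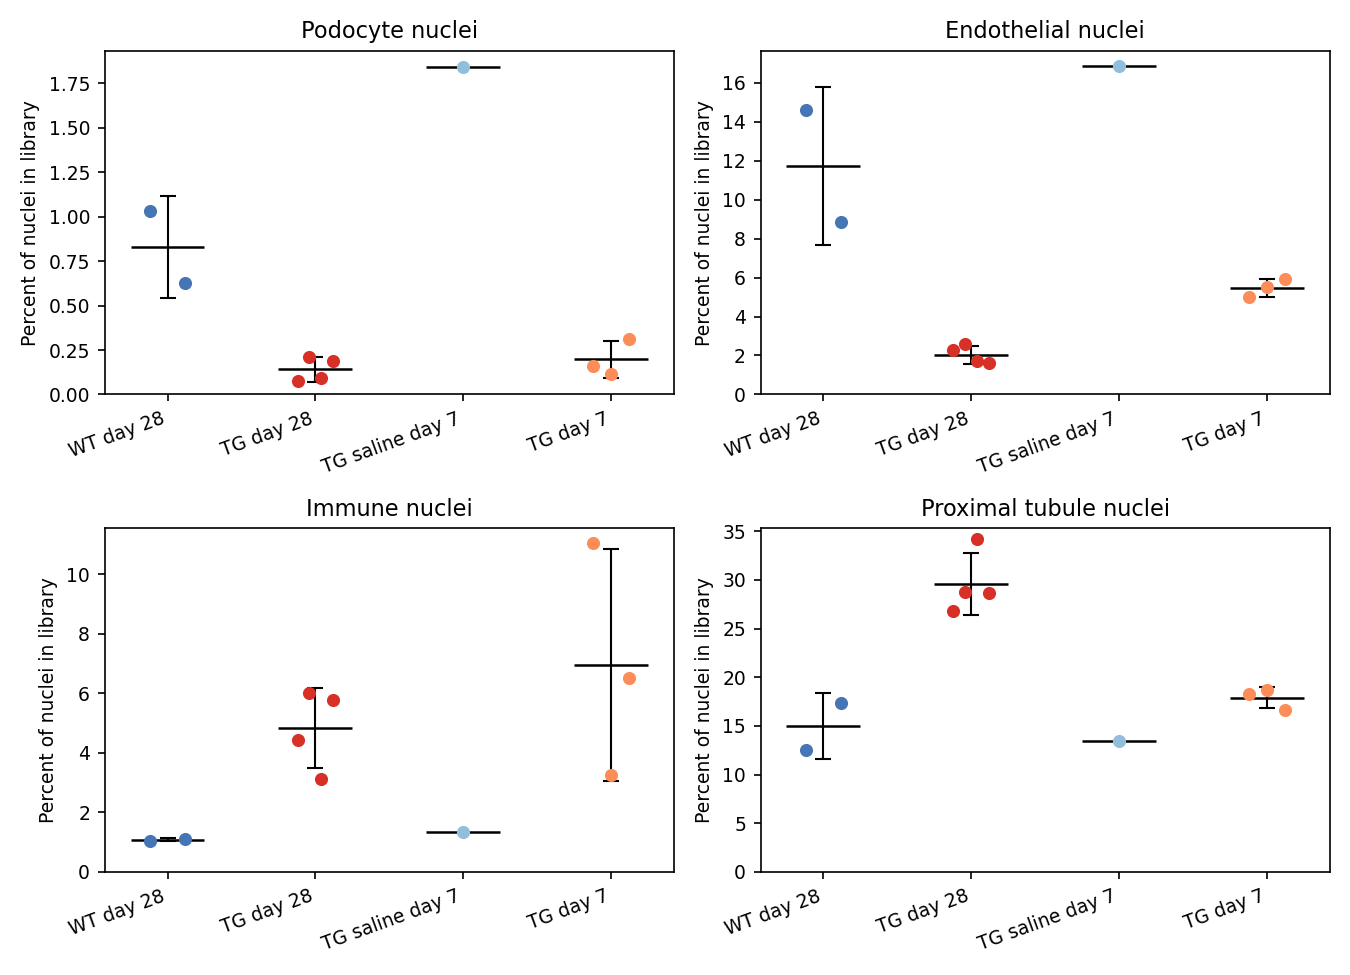
Percent of nuclei per library (vertical axis) in 4 classes, by group (horizontal axis); points are libraries, horizontal lines group means and bars SD, absent for the group with 1 library. Endothelial shares were 11.7% on average in wild-type and 2.03% in treated libraries at day 28.

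At day 7 the podocyte share was 0.197% ± 0.103 (SD, n = 3) after treatment, against 1.85% in the saline library, whose exact binomial 95% interval of 1.59% to 2.13% covers counting error only. The log2 ratio was -3.23 ± 0.54 (edgeR adjusted p = 0.0018). Endothelial nuclei fell by 1.62 ± 0.20 on the log2 scale, macula densa nuclei by 2.52 ± 0.45 and thick ascending limb nuclei by 0.92 ± 0.29. The macula densa value rests on 16, 19 and 8 treated nuclei against 76 in the saline library. The wild-type libraries held 0.945% and 0.373% of this class, so its share also varied between controls. Immune nuclei rose by 2.37 ± 0.70 and principal cells of the collecting duct by 0.79 ± 0.25. The proximal tubule log2 ratio of 0.41 ± 0.23 did not pass the test (edgeR adjusted p = 0.172). The adjusted p for principal cells was 0.0707 without TG day 7 replicate 3, 0.0542 without TG day 28 replicate 3 and just above 0.05 without either wild-type library, and that for thick ascending limb 0.0707 without TG day 7 replicate 3. With 1 control library, the spread of that library was assumed to be like that of the other groups.

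In proximal tubule nuclei at day 28, 23 of 24 injury, 18 of 18 NF-kB and chemokine and 6 of 7 complement genes rose, and 10 of 12 organic ion and 5 of 6 water transport genes fell. These list calls were lost with an estimated correlation (adjusted p = 0.241, 0.241, 0.261, 0.241 and 0.261 in that order). Havcr1, the kidney injury molecule, was 105 CPM in treated and 6.48 CPM in wild-type libraries (log2 fold change 4.09 ± 0.31 SE, edgeR adjusted p = 5.5e-06), and was 12.1 and 30.4 times the control within batches 1 and 2. In GRCm38, with genes from GENCODE M21, Havcr1 (ENSMUSG00000040405) lies on chromosome 11 from 46735080 to 46779578. Spp1, which encodes osteopontin, rose by 4.11 ± 0.36, the adhesion molecule Vcam1 by 5.31 ± 0.65, the chemokine Cxcl1 by 5.59 ± 0.35 and the inflammatory caspase Casp4 by 5.51 ± 0.35. Areg, a growth factor of the EGF receptor, had 0 control counts and was at least 57.8-fold higher against a floor of 3 counts over the group. The transcription factor Sox9 had 3 control counts, a ratio of 146 with a counting interval of 49.9 to 707. Lpl, a lipase, fell by 5.85 ± 0.22, the cadherin-linked gene Ctnna2 by 4.10 ± 0.35 and the water channel Aqp4 by 4.25 ± 0.31. In all, 4848 of 15074 genes changed, 2635 up and 2213 down. The count was 2167 without WT day 28 replicate 2, and 2406, with 730 up and 1676 down, when only genes at or above their level over all nuclei were tested, an alternative chosen after the data were seen.

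These sums mixed clusters whose shares differed between groups. The injured cluster, with Havcr1, Vcam1 and Cxcl2 among its leading genes, held 0.502% of wild-type and 3.86% of treated nuclei on average, and without it 4126 genes changed. Its size depended on the correction between libraries. With clustering without correction, a cluster also named injured held 0.384% and 0% of wild-type and 9.9% to 13.0% of treated day 28 nuclei. Over clusters 9, 10 and 13 alone 1778 genes changed, 984 up and 794 down; this choice leaves out nuclei in which the segment markers are low. There Havcr1 rose by 3.30, Spp1 by 3.71, Cxcl1 by 5.67 and C3 by 5.84, and Lpl fell by 5.02 (edgeR adjusted p = 7.0e-04, 5.4e-06, 3.3e-05, 3.2e-06 and 5.4e-07). Of the rises named here, Anxa2 was 1.86, Birc3 2.06, Klf6 2.54 and Relb 3.16 there, against 4.13, 3.47, 3.72 and 3.87 over the whole class, and of the falls Slc22a7 was -3.70, Ctnna2 -3.06 and Csf1r -1.42, against -4.79, -4.10 and -2.10; all 7 passed. Areg was at least 10.8-fold higher there, and with 2 control counts each Casp4 had a ratio of 24.2 (counting interval 6.71 to 200.2) and Vcam1 of 168 (46.6 to 1391). The phosphate transporter gene Slc34a1 fell by 1.15 over the class, and was -0.25 there without passing (edgeR adjusted p = 0.461). Of the lists, 16 of 23 injury, 13 of 16 NF-kB, 4 of 6 complement, 10 of 12 interferon and 3 of 20 TGF-beta genes rose, while 2 of 5 S2, 4 of 6 water transport and 5 of 13 thick ascending limb genes fell. Of 12 organic ion transporters 3 fell and 1 rose, of 9 S3 genes 5 fell and 1 rose, and of 8 gluconeogenesis genes 1 fell and 1 rose, with a median log2 fold change of 0.10 in the last list.

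Of 28 gene lists fixed beforehand and tested with camera, 13 passed at day 28, 7 up and 6 down, and 0 with an estimated correlation, where the lowest adjusted p = 0.241. In these, 23 of 24 tubule injury genes rose at day 28, also adjusted over the list alone; the transcription factor gene Klf6 and the annexin gene Anxa2 rose by 3.72 and 4.13. All 18 NF-kB and chemokine genes rose, with 18 adjusted over the list alone, among them Relb by 3.87 ± 0.27 and Birc3 by 3.47 ± 0.25. In the complement list 6 of 7 rose (6 adjusted over the list alone), including C3 by 5.22 ± 0.34, which was 19.4 and 106 times the control within batches 1 and 2. Interferon and antigen presentation genes rose in 14 of 15 (15 adjusted over the list alone), and TGF-beta and matrix genes in 14 of 21 (19 adjusted over the list alone). With an estimated correlation the list calls were lost, with adjusted p = 0.241 for the injury, NF-kB and interferon lists, 0.261 for complement and 0.258 for the TGF-beta list. Of 10 p53 response genes 5 rose (5 adjusted over the list alone) and of 10 macrophage markers 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.241 and 0.452 with an estimated correlation). Macrophage markers moved beside these groups, with Cd74 up by 3.23 ± 0.37 and Csf1r down by 2.10 ± 0.36 in proximal tubule nuclei. Within batches 1 and 2 the ratio to the control was 10.3 and 25.1 for Relb, 7.80 and 17.6 for Birc3, 35.6 and 65.5 for Casp4, 13.7 and 26.0 for Anxa2, 7.57 and 13.0 for Cd74 and 0.442 and 0.143 for Csf1r; Vcam1 was 16.5 times the control in batch 1, and its control in batch 2 was at 0.

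The 6 falling lists at day 28 were the S2 and S3 segment genes, organic anion and cation transport, gluconeogenesis, water transport and thick ascending limb genes. Of 12 organic anion and cation transporters 10 fell (10 adjusted over the list alone), among them Slc22a7 by 4.79 ± 0.41, and Abcc4 rose by 2.57 ± 0.15; the list p was 0.241 with an estimated correlation. All 5 genes of the S2 list fell and 6 of 9 of the S3 list (5 and 8 adjusted over the list alone; adjusted p = 0.338 and 0.426 with an estimated correlation); these genes also served as class markers. Gluconeogenesis genes fell in 5 of 8, with the pyruvate carboxylase gene Pcx down by 0.96 ± 0.15 (6 adjusted over the list alone; adjusted p = 0.420 with an estimated correlation). Of 14 cholesterol synthesis genes 5 fell (5 fell and 1 rose adjusted over the list alone), a list that did not pass camera (adjusted p = 0.0574). Of 6 water transport genes 5 fell (5 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation). Lrp2, the endocytic receptor megalin, on chromosome 2 from 69424340 to 69586065, fell by 1.36 ± 0.27 and its partner Cubn by 0.71 ± 0.25, and Pcx, Lrp2 and Cubn were -0.21, -0.64 and -0.071 over clusters 9, 10 and 13 and did not pass there (edgeR adjusted p = 0.357, 0.107 and 0.894), while the glucose transporter Slc5a2 had a log2 fold change of -0.23 ± 0.22 and did not pass the test. Within batches 1 and 2 the ratio to the control was 0.306 and 0.510 for Lrp2, 0.0128 and 0.0226 for Lpl and 0.0703 and 0.0433 for Aqp4. The glycolytic enzyme Hk1 rose by 1.41 ± 0.20, but measured -0.025 when doublets were kept. Distal genes also fell in these nuclei, 8 of 13 in the thick ascending limb list (9 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation), Egf by 3.04 ± 0.38 and Umod by 1.27 ± 0.23. Thick ascending limb nuclei made up 23.5% of wild-type and 16.0% of treated nuclei at day 28, a difference that did not pass (edgeR adjusted p = 0.0562). The genes of this list fell in them too. Free RNA from that class may therefore give this fall in proximal tubule nuclei, which was not tested.

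**Figure D2:**
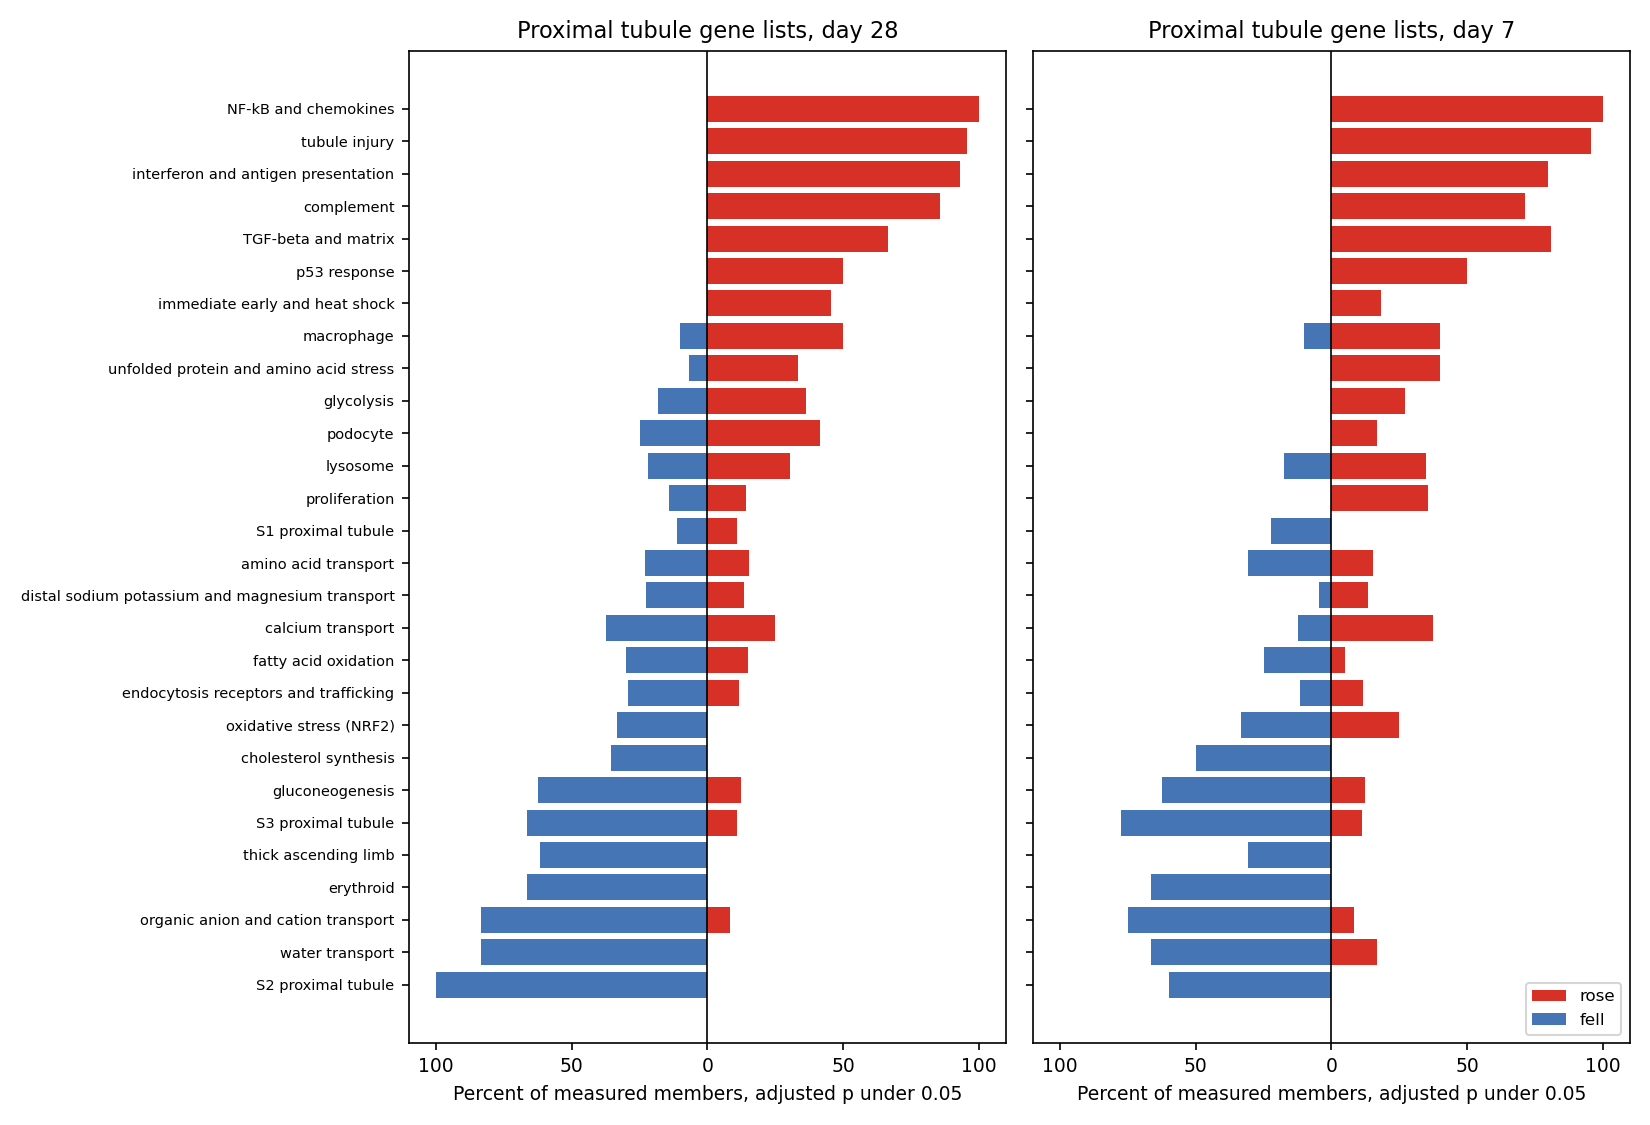
Percent of measured members of each fixed gene list (vertical axis) that rose (red, right) or fell (blue, left) in proximal tubule nuclei at adjusted p under 0.05 (horizontal axis), at day 28 and day 7. All 18 NF-kB and chemokine genes rose at both days.

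At day 7 the proximal tubule showed 3044 changed genes, 1568 up and 1476 down. Havcr1 rose by 4.61 ± 0.43 (edgeR adjusted p = 1.1e-04), Spp1 by 4.22 ± 0.50 and Cxcl1 by 6.04 ± 0.50. The chemokine Cxcl2 was at least 65.6-fold higher, the stress-response gene Ankrd1 at least 62.8-fold and the guanylate-binding protein Gbp5 at least 37.4-fold, each against a floor of 3 counts over the group. Over clusters 9, 10 and 13, which held 20, 32 and 13 treated counts of Cxcl2, Ankrd1 and Gbp5 and 0 control counts, the bounds were 4.21, 6.74 and 2.74, and Ankrd1 passed (edgeR adjusted p = 0.0209) while Cxcl2 and Gbp5 did not (0.111 and 0.109). Slc34a1 fell by 1.24 ± 0.31 and the amino acid transporter Slc7a13 by 3.34 ± 0.54, while the log2 fold change of Lrp2 was -0.83 ± 0.36 and did not pass (edgeR adjusted p = 0.123). At day 7 16 lists passed camera, 9 up and 7 down, and 0 with an estimated correlation. Again 23 of 24 injury genes and 18 of 18 NF-kB genes rose (23 and 18 adjusted over the list alone), with an adjusted p = 0.149 with an estimated correlation for both. Proliferation genes rose in 5 of 14 (9 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation), with Diaph3 up by 4.46 ± 0.41. Nuclei of unnamed cluster 23, with Top2a and Mki67 among its leading genes, were counted in no class. That cluster held 0.185% of saline and 2.13% to 2.98% of treated day 7 nuclei, so proliferation within a class was measured without them. Cholesterol synthesis genes fell in 7 of 14, Hmgcs1 by 2.07 ± 0.25 (8 adjusted over the list alone; adjusted p = 0.312 with an estimated correlation). The count was 1730, with 525 up and 1205 down, when only genes at or above their level over all nuclei were tested, and 1111 over clusters 9, 10 and 13. In those clusters Havcr1 rose by 2.32, Diaph3 by 3.47, Slc7a13 fell by 2.41, 13 of 23 injury, 8 of 16 NF-kB and 2 of 12 proliferation genes rose, 3 of 14 cholesterol genes fell, and Slc34a1 was -0.41 and did not pass (edgeR adjusted p = 0.364).

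**Figure D3:**
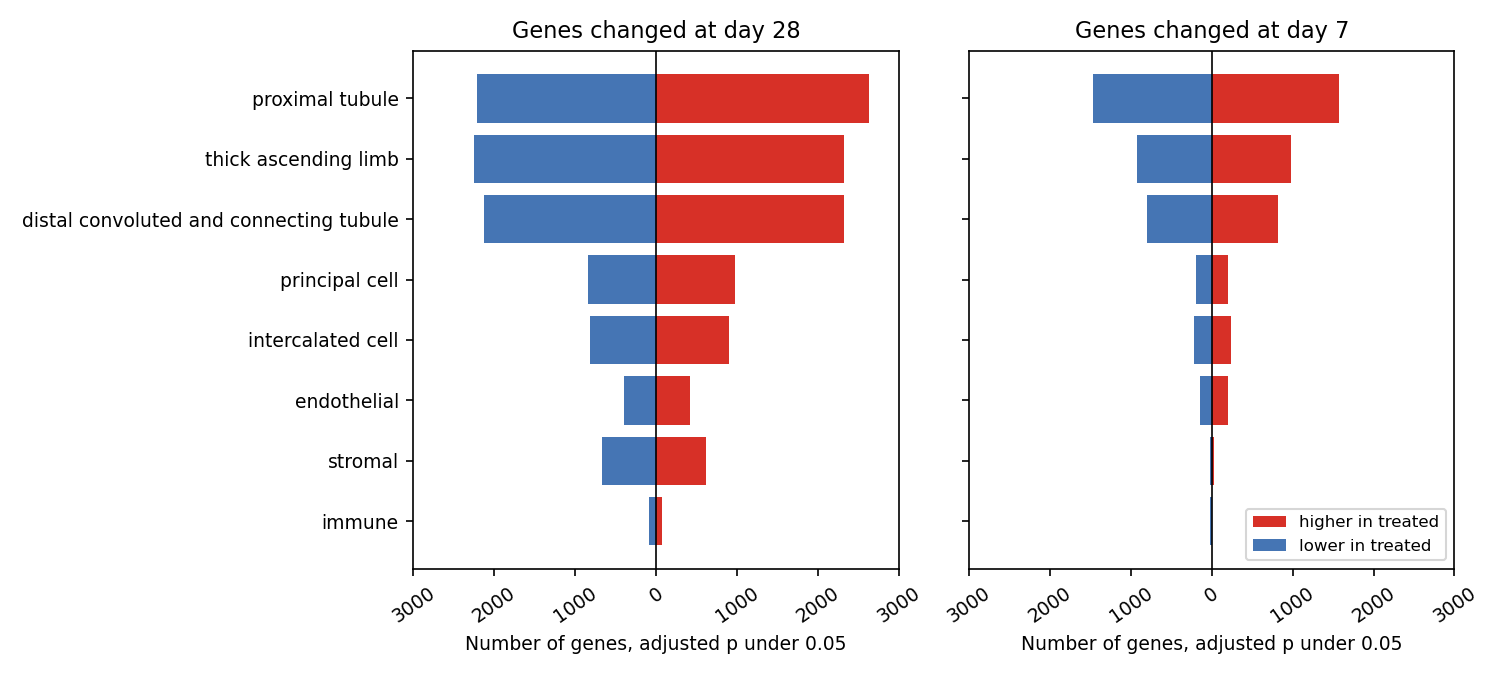
Number of genes higher (red, right) and lower (blue, left) in treated libraries at adjusted p under 0.05 (horizontal axis, same scale in both panels) per cell class (vertical axis). Proximal tubule had 4848 changed genes at day 28 and 3044 at day 7.

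The 2 days shared much of the proximal tubule response. Of the genes that rose, 1292 did so at both days, where independent lists would share 274, and of those that fell 1141 did, against 217; 0 rose at day 28 and fell at day 7, and 5 did the reverse. The days used different control libraries but came from 1 fit with 1 estimate of spread per gene. A gene with a low spread is called more easily at both days. Some overlap above the independent number can therefore arise without a shared response. Lpl and the cell adhesion gene Lsamp, named after their values were seen, were the 2 genes whose change differed between days: Lpl fell by 5.85 at day 28 and by 2.59 at day 7, and Lsamp fell by 1.18 at day 28 and rose by 1.33 at day 7. That difference is confounded with the controls' genotype, batch and day, and the count was 48 with DESeq2, 319 without a low-count filter, and 0 when any 1 of the TG day 28 replicates, TG day 7 replicate 2 or TG day 7 replicate 3 was left out; it was 1 without WT day 28 replicate 1 and 4 without TG day 7 replicate 1. All treated against all control libraries gave 6067 genes, 3226 up and 2841 down.

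**Figure D4:**
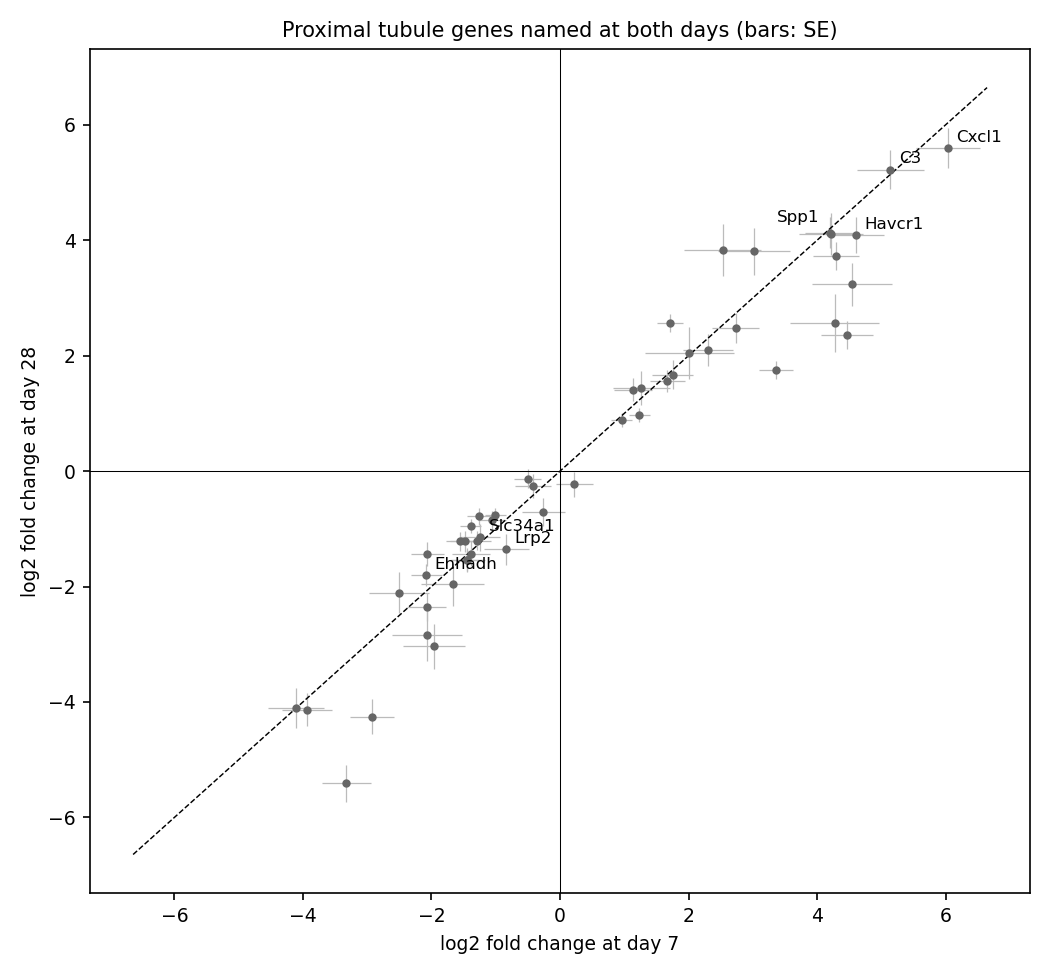
Log2 fold change of named proximal tubule genes at day 7 (horizontal axis) and day 28 (vertical axis) with SE bars and a dashed line of equality; genes with 3 or fewer counts in a control or treated group are left out. Havcr1 was 4.61 at day 7 and 4.09 at day 28.

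Between nuclei of the S1-like and S3-like clusters, the response differed for 1294 genes at day 28 and 476 at day 7. S1-like cluster 2 had 8649 nuclei against 3502 in cluster 13, and matched 3 of 6 S1 markers with 0 among its 10 leading genes. These counts therefore do not measure position along the tubule alone. Each segment joined clusters whose shares differed by group: S1-like cluster 2 held 3.00% and 3.45% of wild-type and 9.86% to 13.0% of treated nuclei at day 28, and S3-like cluster 20 held 0.541% and 1.67% against 2.52% to 2.99%. Between clusters 13 and 10 alone the counts were 449 and 239. Slc34a1 fell by 1.66 ± 0.26 in S1 and was -0.63 ± 0.24 in S3, a difference of -1.03 ± 0.13 (edgeR adjusted p = 1.6e-06); the S3 value did not pass (adjusted p = 0.0681). In cluster 13 alone Slc34a1 was -0.54 ± 0.19 and in cluster 10 -0.038 ± 0.23, and neither passed (edgeR adjusted p = 0.0807 and 0.961); their difference was -0.51 ± 0.15 (adjusted p = 0.0391). For Havcr1 the segments had 4.22 ± 0.56 in S1 and 5.29 ± 0.31 in S3, a difference of -1.07 ± 0.79 that did not pass (edgeR adjusted p = 0.490), and in cluster 13 alone it was 2.56 ± 0.84 and did not pass (adjusted p = 0.0652). The day 28 count was 583 without WT day 28 replicate 2 and 509 with DESeq2, and the day 7 count 218 with DESeq2.

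In the thick ascending limb 4581 genes changed at day 28 and 1899 at day 7. Its own genes fell in 11 of 13 at day 28, Egf by 2.96 ± 0.27 and the prostaglandin receptor Ptger3 by 1.86 ± 0.17, while 18 of 23 injury genes rose and 1 fell (11 fell in the first list, and 19 rose and 1 fell in the second, adjusted over the list alone; adjusted p = 0.334 and 0.299 with an estimated correlation). Lcn2, an iron-binding injury protein, rose by 6.42 ± 0.48 at day 28. The count at day 28 was 2344 without WT day 28 replicate 2 and 2779 without WT day 28 replicate 1. The sums of this class also mixed clusters whose shares differed by group. At day 28 cluster 0 held 46.7% and 49.5% of the class in wild-type and 54.8% to 60.3% in treated libraries.

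In the distal convoluted and connecting tubule 4447 genes changed at day 28 and 1625 at day 7. The make-up of this class differed by group. Cluster 21, with Calb1, Trpm6 and Wnk1 among its leading genes, held 16.2% and 12.9% of it in wild-type and 8.32% to 9.72% in treated libraries at day 28. The calcium-binding protein genes Pvalb and Calb1 fell by 5.19 ± 0.33 and 2.78 ± 0.14, Egf by 5.04 ± 0.50, the magnesium channel Trpm6 by 2.31 ± 0.12 and the kinase Wnk1 by 2.45 ± 0.14. Of 22 distal sodium, potassium and magnesium transport genes 15 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 0.349 with an estimated correlation). Without WT day 28 replicate 2 the count was 2371, and without WT day 28 replicate 1 2488.

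In principal cells 1819 genes changed at day 28 and 393 at day 7. The vasopressin receptor Avpr2 fell by 1.41 ± 0.20 at day 28 and Clu, a secreted chaperone, rose by 4.61 ± 0.38. In intercalated cells 1721 and 459 genes changed, with Cadps down by 4.86 ± 0.32 and the cytokine gene Il34 up by 2.00 ± 0.17 at day 28. Intercalated cluster 12 held 51.3% and 48.1% of the class in wild-type and 61.0% to 65.2% in treated libraries at day 28. Cluster 17, with Slc26a4 among its leading genes, held 38.5% and 41.4% against 27.1% to 29.9%. Principal cell counts at day 28 were 551 and 633 without WT day 28 replicates 2 and 1 and 1145 without TG day 28 replicate 2. Intercalated cell counts were 630 and 783 without those wild-type libraries and 974 with DESeq2.

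Endothelial nuclei showed 816 changed genes at day 28 and 355 at day 7. Their make-up differed by group at day 28: cluster 8 held 57.4% and 59.3% of the class in wild-type and 49.0% to 60.2% in treated libraries, cluster 22 held 31.0% and 29.7% against 13.5% to 22.0%, and cluster 27, with Sox17, Bmx and Eln among its leading genes, held 11.5% and 11% against 21.7% to 31.8%. At day 7 cluster 22 held 28.1% in the saline and 17.2% to 22.2% in treated libraries, and cluster 27 10.0% against 12.5% to 18.2%. At day 7 Top2a, a DNA topoisomerase, rose by 4.05 ± 0.64, and 3 of 8 proliferation genes rose (6 adjusted over the list alone, adjusted p = 0.0809 with an estimated correlation). Unnamed cluster 23, led by Top2a, was not part of this class. Stromal nuclei had 1287 at day 28, with the latent TGF-beta binding gene Ltbp2, which had 0 control counts, at least 15.7-fold higher against a floor of 3 counts over the group, and 46 at day 7. The stromal class lay in different clusters by group: cluster 19 held 37.4% and 46.0% of it in wild-type and 78.0% to 87.7% in treated libraries at day 28, while cluster 31, with Myh11 among its leading genes, held 33.2% and 27.4% against 7.67% to 13.5%, and cluster 32, with Ren1 among its leading genes, held 29.4% and 26.5% against 4.65% to 9.33%. In cluster 19 alone, an alternative chosen after the data were seen, 707 genes changed at day 28, and Ltbp2 was at least 6.0-fold higher (edgeR adjusted p = 7.2e-04). Immune nuclei had 161 and 30. Endothelial counts at day 28 were 301 and 403 without WT day 28 replicates 2 and 1 and 501 without TG day 28 replicate 2, and at day 7 226 and 217 without TG day 7 replicates 1 and 3. Stromal counts were 602 and 513 without those wild-type libraries, and 76 at day 7 without TG day 28 replicate 4. Immune counts were 10 and 31 without them at day 28, and at day 7 ranged from 10 to 129 when libraries were left out.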

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

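The Egf test and the depth test scaled to each library were chosen after the patterns were seen, as were the values over clusters 9, 10 and 13; the macrophage test and the UMI minimum were revised after related values had been seen, and before their own results.

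The treated and control libraries differed in 6067 proximal tubule genes, and 1 of 100 splits of the 10 libraries into 7 and 3, the real one, gave as many; the highest of the other splits gave 0 genes at the adjusted threshold, and 3643 at an unadjusted p under 0.05 against 7288 for the real split. The other splits moved libraries between groups without regard to batch, and all mixed treated with control libraries, which widens the spread within groups. They show that no other grouping tried gave as many genes, and they cannot exclude chance.

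Endothelial nuclei were fewer in treated libraries. Growth of other classes alone does not account for it: without proximal tubule, immune and unnamed nuclei, and with the stromal-marker cluster kept, the day 28 log2 ratio was -1.96 ± 0.13 (SE). With the UMI minimum scaled to each library's median, from 500 in the shallowest to 1037 in the deepest, it was -2.36 ± 0.13, which argues against depth as the whole cause. A fixed minimum of 1000 UMIs gave -2.65 ± 0.48 but left out 12.3% to 40.9% of nuclei per library, so it decides nothing. Unequal recovery of endothelial nuclei during dissociation or sorting was not tested and stays open beside a biological loss in treated mice, so this may be either.

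NF-kB and chemokine genes rose in proximal tubule nuclei at day 28. Their rise would need a median 83.5% of immune RNA, while the highest share any low-baseline macrophage marker allows is 16.1%, which argues against macrophage RNA. For each of the 18 genes the log2 fold change outside proximal tubule was subtracted from that in it. The median of these differences was 1.56 ± 0.46, where the error is the spread over genes of the list. These genes come from the same libraries, so the error does not measure spread between mice. Within that limit the value argues against free RNA shared by all nuclei as the whole cause. After thinning all libraries to 3502500 counts 18 of 18 genes still rose, which argues against depth, and over clusters 9, 10 and 13 13 of 16 measured members rose, so the larger share of other clusters was not needed for those. A response of the tubule cells may account for the pattern, as a hypothesis found and tested in the same libraries.

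Egf fell in principal, intercalated, endothelial and stromal nuclei at day 28 by 2.37, 2.47, 2.38 and 2.58 on the log2 scale, and over all nuclei by 3.84 ± 0.43. In 3 of these 4 classes the fall lay more than 2 SE from that over all nuclei, with the 2 errors taken as independent. The sum over all nuclei includes nuclei that make Egf, so it is not a measure of free RNA. The comparison therefore cannot decide the question. The 4 falls lie close together, as RNA from 1 source could give, so free RNA stays open as part or all of the pattern.

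Of 115 groups of 4 treated day 28 libraries tested, 9 had a library far from the others, where chance gives about 5.75. These were the stromal share with a value of 2.01%, and in proximal tubule Npc2 with 23.1 CPM, Klf6 with 139 CPM, Pcx with 132 CPM, Cenpe with 5.42 CPM, Slc12a3 with 22.4 CPM, Hbb-bs with 8.73 CPM, Hba-a1 with 9.40 CPM and Spp1 with 388 CPM.

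The change differed between day 7 and day 28 for 2 genes in proximal tubule, 52 in thick ascending limb, 20 in distal convoluted and connecting tubule, 4 in principal cells, 27 in intercalated cells, 42 in endothelial nuclei, 180 in stromal nuclei, 1 in immune nuclei and 32 in the stromal-marker cluster. It differed between S1-like and S3-like nuclei for 1294 genes at day 28 and 476 at day 7, and between clusters 13 and 10 alone for 449 and 239. The S1-like nuclei included cluster 2, which had 0 S1 markers among its 10 leading genes.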

How the results depend on the processing

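The alternatives that left out the injured cluster, included the stromal-marker cluster, kept only clusters 9, 10 and 13, kept only stromal cluster 19 or restricted proximal tubule genes by level were chosen after the data were seen; the others were set before the data were examined. No paired analysis was possible because the labels' replicate numbers do not pair libraries across groups. The day 7 comparison could not be fitted without the saline library. The causes of the changes between settings given here were not tested.

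With genes at or above their level over all nuclei the counts at day 28 and day 7 were 2406 and 1730 in proximal tubule, 2297 and 1030 in thick ascending limb, 1938 and 786 in distal convoluted and connecting tubule, 765 and 207 in principal cells, and 874 and 203 in intercalated cells; at day 7 they were 217 in endothelial and 28 in stromal nuclei. With DESeq2 they were 974 and 204 in intercalated cells, 450 and 112 in endothelial, 817 in stromal at day 28, 19 in immune at day 7, 48 for the difference between days, and 509 and 218 between segments. Without a low-count filter they were 886 in principal cells and 151 in stromal nuclei at day 7, 340 and 159 in immune nuclei, and 319 for the difference between days, which was 0 without a batch term and 1 with clustering without correction. Rises and falls with genes at or above their level over all nuclei were 580 and 1717 in thick ascending limb and 552 and 1386 in distal convoluted and connecting tubule at day 28. Over clusters 9, 10 and 13 the counts were 1778 and 1111 in proximal tubule and 449 and 239 between segments, the log2 ratio of proximal tubule shares was 0.19 at day 28 and -0.41 at day 7, and log2 fold changes were 0.72 for Slc5a12 and 0.41 for Slc5a2 at day 28, and 0.34 for Cubn and 0.25 for Slc5a12 at day 7. With clustering without correction the podocyte log2 ratio was -4.98 at day 28. Stromal day 7 with the stromal-marker cluster was 282, and stromal day 28 in cluster 19 alone 707. Lists called with an estimated correlation were 0 at both days. The log2 fold change of Hk1 in proximal tubule at day 28 was -0.025 with doublets kept. That of Alas2 was -0.72 without WT day 28 replicate 1 and 0.33 without WT day 28 replicate 2.

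Leaving out each library gave, for day 28 and day 7, 2167 to 4838 and 2355 to 3209 genes in proximal tubule, 2344 to 4726 and 1472 to 1977 in thick ascending limb, 2371 to 4582 and 1212 to 1725 in distal convoluted and connecting tubule, 551 to 1828 and 274 to 460 in principal cells, 630 to 1869 and 324 to 514 in intercalated cells, 301 to 829 and 217 to 423 in endothelial, 513 to 1396 and 41 to 76 in stromal, and 10 to 240 and 10 to 129 in immune nuclei. The difference between days gave 0 to 4, segments 583 to 1339 and 370 to 597, the podocyte log2 ratio at day 28 -2.85 to -2.17, that of proximal tubule 0.85 to 1.15, and classes with changed shares at day 28 1 to 8.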

Other observations

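The lists and the rule for genes below were fixed before the data were examined, and which of them to describe here was chosen after their results were seen. In endothelial nuclei 8 of 18 TGF-beta and matrix genes rose at day 28 and 11 at day 7, and 12 and 11 of 21 injury genes (8, 14, 13 and 18 rose and, at day 7, 1 TGF-beta and matrix gene fell adjusted over the list alone; adjusted p = 0.335, 0.0809, 0.187 and 0.0624 with an estimated correlation, in that order). These sums mixed clusters whose shares of the class differed by group, cluster 27 holding 11.5% and 11% of it in wild-type and 21.7% to 31.8% in treated libraries at day 28, and 10.0% against 12.5% to 18.2% at day 7. In intercalated cells the cytokine regulator Socs3, which had 0 control counts, was at least 23.0-fold higher at day 28 against a floor of 3 counts over the group, and Oasl2, an interferon-induced gene, rose by 3.67 ± 0.44. In proximal tubule nuclei 2 genes of the podocyte list rose at both days, Synpo by 3.81 ± 0.41 and Thsd7a by 3.82 ± 0.45 at day 28; over clusters 9, 10 and 13, chosen after the data were seen, Synpo and Thsd7a rose by 2.01 and 2.41 at day 28, and at day 7 Thsd7a rose by 1.58 and Synpo was 1.17 without passing (edgeR adjusted p = 0.349). The list did not pass camera at either day (adjusted p = 0.873 and 0.239). Synpo encodes an actin-associated protein.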
